A study of Mus musculus with 1248 samples.

How the data were processed

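Single-cell RNA sequencing of 1248 sorted wells from 6 B2905 melanoma tumours was analysed from 2 deposited expression tables, with a deposited list of expressed variants described over the whole series only. Libraries were made by Smart-seq2, per the labels' protocols, which yields unstranded full-length libraries without molecular identifiers. The submitters' processing notes name Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.2, Picard 2.22.3 and GATK and the builds GRCm38 and mm10, without parameters; which annotation was used is not given in the sources used here. The deposited estimated counts per gene need not be whole numbers and were the basis of all main results. The deposited TPM values, scaled by the authors to a fixed sum per cell, were used as an alternative. Another expression table, in FPKM, was not used here. The tables hold 55401 genes, of which 55141 matched the GENCODE annotation of GRCm38 by identifier, and coordinates, gene types and exon overlaps come from it. Where a symbol stood for several genes, the one with the highest mean was used.

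The deposited variant list holds calls of cells one after another without cell names, read numbers or coverage. Calls could not be tied to cells or tumours without relying on their order, so the planned shares of mutated cells, their relation to the scores, and whether tumour cells carry expressed mutations are not reported here.

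Each well's tumour and plate were taken from its label. The labels do not say which tumours were treated, so the 6 tumours are the groups, each from 1 mouse, and the cells of a tumour are not replicates. Plates are nested in tumours: 3 plates each for tumours 103, 109 and 115, 2 for tumour 117 and 1 each for tumours 107 and 122. Wells were kept with at least 1500 detected genes (a count of 1 or more), at least 100000 counts and at most 25% of counts from mitochondrially encoded genes. Of the 421 wells left out, 356 failed on genes or counts and 65 on the mitochondrial share alone. Cells had been sorted into wells, so no doublet caller was run, and an alternative left out the 5% of cells with most genes in each tumour. Shares of cells have exact Clopper-Pearson 95% intervals. All intervals and limits cover counting error only.

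Kept cells were clustered on log2(CPM + 1) of the 2000 most variable genes, with 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A cluster took the name of the class with the largest share of markers detected in at least 50% of its cells, if at least 50% of the markers and at least 3 were detected and its 10 leading genes held no more markers of another class than of that class. The classes with fixed markers were melanoma, fibroblast, pericyte or smooth muscle, endothelial, macrophage or monocyte, dendritic, T or NK, B, neutrophil, keratinocyte, Schwann, erythroid, adipocyte and skeletal muscle cells. Clusters were found for the first 3 of these only. Cells in clusters without the name of another type than melanoma, 794 in all, were kept as tumour cells, unnamed clusters included; these hold 222 cells. Leading genes of a cluster define it and are not results.

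For each tumour, log2(CPM + 1) of each gene was regressed across tumour cells on a score, with the number of detected genes and the plate as covariates. The score was the mean of within-tumour z-values of the fixed genes, the tested gene left out, scaled to an SD of 1. Score genes and tested genes had to be detected in at least 10% of kept cells in every tumour, which left 10760 genes and 16 of 20, 23 of 41 and 69 of 94 score genes for the melanocytic, interferon and cell cycle scores. Slopes are on a log scale with a pseudocount of 1 and understate changes of genes near 0. The 6 slopes per gene were tested against 0 with limma 3.58.1 (trended, two-sided), with Benjamini-Hochberg adjustment over all genes but the score genes, at 0.05. Lists were tested with camera of limma on the same slopes without score genes, with a preset correlation of 0.01 and, as alternatives, an estimated correlation and fry, adjusted over all 43 pairs of list and score. A score and the lists tested along it were measured in the same cells, so slopes are associations. Levels between tumours are CPM of counts summed over tumour cells, in which deep cells weigh more.

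The same steps were tested on simulated data, in which values were permuted within tumour and plate and 200 of 10760 genes given known slopes. All 33 genes at 1 and all 33 at -1 were recovered, 44.1% and 63.6% at 0.5 and -0.5, and 26.5% and 24.2% at 0.25 and -0.25, with 4 false calls among 10560 unchanged genes. Each gene was permuted separately, which removes correlation between genes, and a changed gene had the same slope in every tumour. These rates need not hold for the real cells.

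Alternatives were partial Spearman correlation, a pseudocount of 10, gene filters at 25% and 1% of cells, no covariate for detected genes or for plate, stricter cell filters of 3000 genes and 300000 counts, all kept cells, melanoma-like clusters alone, TPM, pooled size factors of scran 1.30.0, weights by number of cells, leaving out each tumour, and a quasi-likelihood test of edgeR 4.0.16 on rounded counts summed over the cells above and below the median score of each tumour, with the tumour as a block. These ranges of a score are not cell types. For levels they were means over cells, TMM factors, TPM, stricter cell filters, all kept cells and leaving out each plate; for shares, resolutions of 2 and 0.5. When a tumour was left out, the gene filter was kept. Analyses without cluster 6, without cluster 9, of melanoma-like cells without tumour 122, and of levels without tumour 122 were chosen after seeing the data, as were those of the Y-linked score without 1 tumour or the covariate of detected genes.

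Groups, designs, cell filters, gene lists, cell type markers, alternatives and the rule for named genes were fixed before the data were examined. The clustering settings, the rule that gives a cluster its name, and the score of Y-linked genes were set later. The named genes are, per score, the 8 with the largest positive and the 8 with the largest negative mean slope among genes that passed with 1 sign in all 6 tumours, and up to 4 members per list with the largest slopes. Between tumours they are the 3 with the largest positive and the 2 with the largest negative log2 ratio to the median of the other tumours, with at least 20 CPM in the higher, detection in at least 25% of cells and at least 0.5 of the log2 ratio in each plate, and Hgf, Met and list members with the largest range over tumours. Score genes, predicted genes, pseudogenes and ribosomal protein genes were left out. Some genes that the rule takes are not reported here. Markers named for clusters and the sex-linked genes were chosen after their values were seen, as was Cdkn2a. Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and in R 4.3.3, with figures by matplotlib 3.10.9.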

Results

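Single cells of B2905 tumours were profiled by Smart-seq2, a plate-based method that copies full-length transcripts of a sorted cell. B2905 is a mouse melanoma line. The labels give the strain as HGF-tg C57BL6, where HGF is hepatocyte growth factor. The cells had been grown under the skin of C57BL/6 mice that received either an IgG2b control antibody or an antibody against CTLA-4, an inhibitory receptor of T cells. Cells were sorted as alive and nucleated, without CD45, a marker of leukocytes, and without CD31, a marker of endothelium. The labels name 6 tumours, 1 per mouse, but not which antibody each mouse received, so no treated and control tumours were compared. Tumours 103, 109 and 115 contributed 3 plates of 96 wells each, tumour 117 contributed 2, and tumours 107 and 122 contributed 1 each. The study states 200 to 300 sorted cells per tumour. Of 1248 wells, 827 (66.3%) held a cell that passed the filters on detected genes, total counts and mitochondrial share. The share of wells kept was 67.4% in tumour 103, 69.8% in tumour 107, 60.8% in tumour 109, 64.2% in tumour 115, 60.9% in tumour 117 and 92.7% in tumour 122.

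The median kept cell had 6736536 estimated gene counts, with a range from 102413 to 81077094, and 6543 detected genes. Median counts per tumour were 6730032 in tumour 103, 5824009 in tumour 107, 12616754 in tumour 109, 7779001 in tumour 115, 6343167 in tumour 117 and 2759882 in tumour 122. Tumour 122 had the lowest median depth, although its median of 6351 detected genes lay near the 6402 to 6721 of the other tumours. Its plate is also the only plate without a number in the labels. With 1 tumour per mouse and the treatments not given, differences between tumours are described without a test. Relations between genes across the cells of a tumour were tested over the 6 tumours, 1 value per tumour.

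The kept cells formed 13 clusters, and most cells were melanoma-like by their markers. Clusters with melanocyte markers such as Sox10 and Mitf, transcription factors of the melanocyte lineage, and Pmel, Tyr and Mlana, genes of pigment formation, held 572 of the 827 cells. Fibroblast-like cells, with Col1a1, Col1a2, Dcn and Lum, formed 1 cluster of 20 cells, and pericyte- or smooth muscle-like cells, with Rgs5, Kcnj8 and Abcc9, formed 1 of 13 cells. Clusters 2, 6, 10 and 11 stayed unnamed, with 12.6%, 8.0%, 3.5% and 2.8% of the kept cells. Clusters 2 and 6 detected too few markers of any class. Clusters 10 and 11 detected 8 and 9 of 12 melanoma markers, but had 1 macrophage marker each among their leading genes: Cd68, detected in 44.8% of cluster 10, and Lyz2, detected in 60.9% of cluster 11 at a mean of 926 CPM. Ptprc and C1qa were detected in 0 cells of either cluster, which allows up to 11.9% and 14.8%. Sox10 was detected in 100% of cluster 2 and of cluster 11 and in 93.1% of cluster 10, but in 37.9% of cluster 6 (exact Clopper-Pearson 95% interval 26.2% to 50.7%) and in 6.1% of the fibroblast- and pericyte-like cells. Ptprc, which encodes CD45, was detected in 1.5% of the 794 cells kept as tumour cells, and Pecam1, which encodes CD31, in 1.9%, after a sort that removed cells with these proteins. Among the named melanoma-like clusters, Cd74 and H2-Aa, genes of MHC class II presentation, were among the leading genes of cluster 7, and cluster 9 had a median mitochondrial share of 10.4% against 3.52% of all kept cells. Cdkn2a, a tumour suppressor often deleted in melanoma, was detected in 0 of the 794 tumour cells, which allows a share of up to 0.46%, and in 4 of the 33 fibroblast- and pericyte-like cells.

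Melanoma-like cells made up similar shares of 5 tumours and a much smaller share of tumour 122. The share was 74.7% of kept cells in tumour 103 (interval 68% to 80.7%), 71.6% in tumour 107 (59.3% to 82%), 76.6% in tumour 109 (69.6% to 82.6%), 76.8% in tumour 115 (70% to 82.6%) and 76.9% in tumour 117 (68.2% to 84.2%). In tumour 122 it was 14.6% (8.0% to 23.7%), 13 cells. Cluster 6 held 67.4% of tumour 122 (56.7% to 77%), and 60 of its 66 cells came from that tumour. It held 3.0% of tumour 107, 1.7% of tumour 117 and 1.1% of tumour 115, 2 cells each, and 0 cells of tumours 103 and 109, which allows up to 1.9% and 2.1%. Cluster 2 was more even, with 9.0% to 15.7% over the 6 tumours. Fibroblast-like cells made up 1.0% to 6.0% and pericyte- or smooth muscle-like cells 0.5% to 2.2% of kept cells, from 1 to 5 cells per tumour and class; the markers used for sorting name neither type. With the clustering resolution halved, 0 cells were pericyte- or smooth muscle-like, and fibroblast-like cells made up 2.7% to 7.5%. A cluster that rests mostly on 1 plate of 1 tumour can be a property of that plate as well as a kind of cell.

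**Figure D1:**
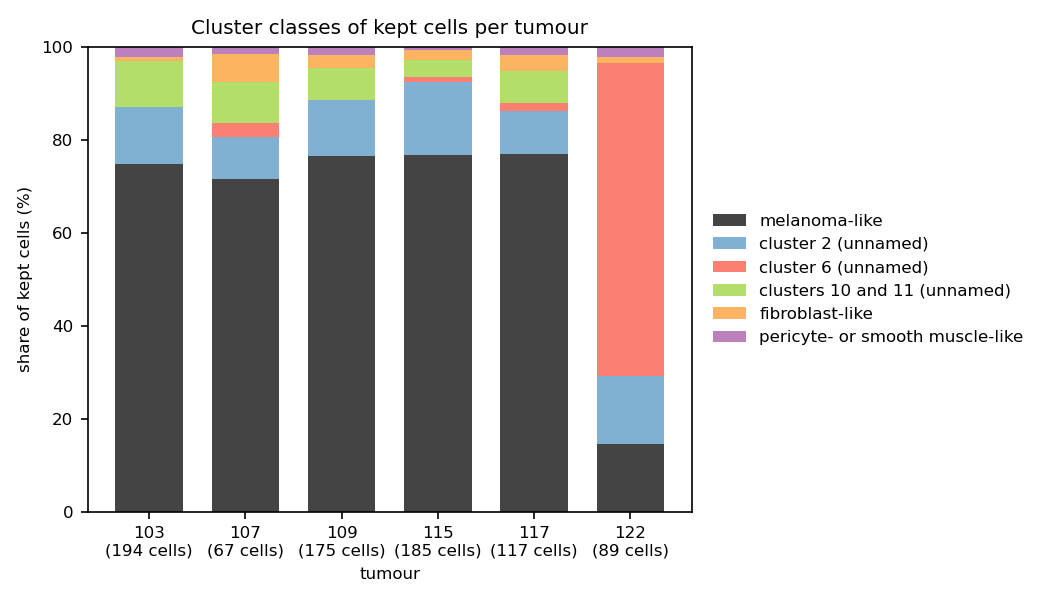
Share of kept cells in each cluster class (vertical axis, percent) for the 6 tumours, with the number of kept cells under each bar. Melanoma-like cells make up 71.6% to 76.9% of 5 tumours and 14.6% of tumour 122, where cluster 6 makes up 67.4%.

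Transcripts of the sex chromosomes differed between the clusters. Xist, the RNA that coats the inactive X chromosome in female cells, was detected in 29 of 33 fibroblast- and pericyte-like cells (87.9%, interval 71.8% to 96.6%) and in 9 of 794 tumour cells (1.1%, 0.5% to 2.1%). In cluster 6 it was detected in 2 of 66 cells (3.0%, 0.4% to 10.5%). At least 1 of the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d was detected in 20.5% of the 794 tumour cells (17.8% to 23.5%). In the melanoma-like clusters 7 and 8 this was 90.3% of cells (83.2% to 95%), and in all other tumour cells 61 of 681 (9.0%, 6.9% to 11.4%). Detection outside clusters 7 and 8 was uneven: it was 27.9% in cluster 2 (19.5% to 37.5%), where Ddx3y was detected in 20.2% and Eif2s3y in 19.2% of cells, 18.8% in cluster 9 and 2.7% in cluster 1, and 32 of 577 (5.5%, 3.8% to 7.7%) outside clusters 2, 7 and 8. The median depth of clusters 7 and 8 was 3984002 and 5474411 counts, within the range of the other clusters of tumour cells, from 2411297 in cluster 11 to 10080027 in cluster 3. The share was 18.1% in tumour 103, 24.2% in tumour 107, 28.1% in tumour 109, 20% in tumour 115, 26.1% in tumour 117 and 2.3% in tumour 122, where no cell belonged to cluster 7 or 8.

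**Figure D2:**
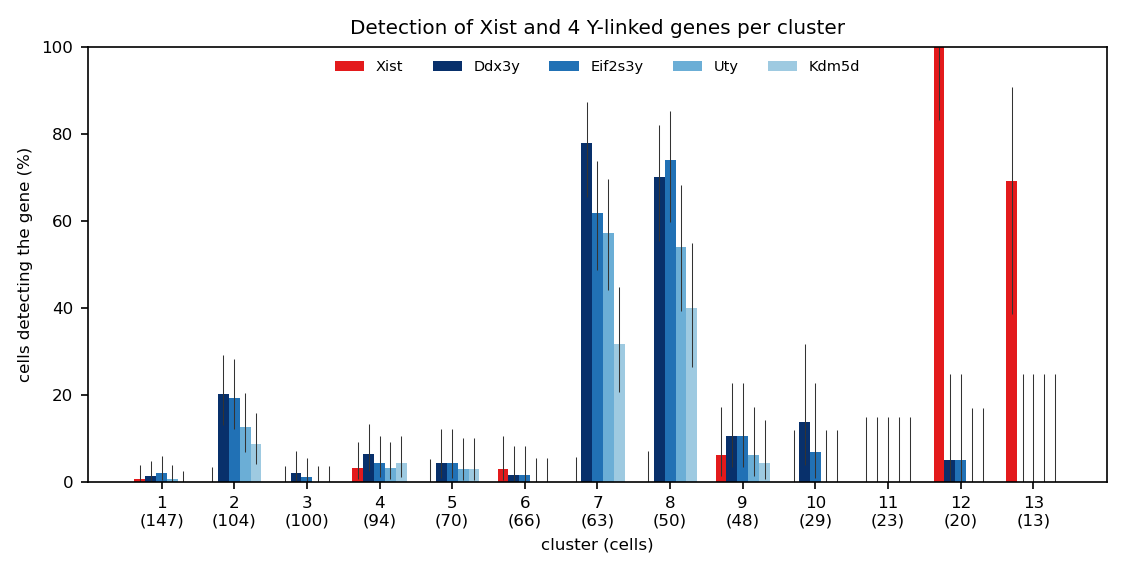
Percent of cells detecting Xist and each of 4 Y-linked genes (vertical axis) in the 13 clusters, with the number of cells under each cluster and exact 95% intervals as thin lines. Xist is concentrated in clusters 12 and 13, the fibroblast-like and pericyte- or smooth muscle-like cells, and the Y-linked genes in clusters 7 and 8, where 90.3% of cells detect any of them.

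The first within-tumour comparison asked which genes follow melanocytic differentiation from cell to cell. The melanocytic score of a cell was the mean of 16 measured genes of the fixed list, such as Mitf, Tyr and Dct. Along it the largest increases were in Tspan10, a tetraspanin, and in Syt4, a synaptotagmin. Tspan10 had a slope of 3.37 ± 0.12 log2 units per SD of the score (limma with Benjamini-Hochberg adjustment, adjusted p = 1.02e-06), or 10.3-fold per SD. Syt4 had 2.99 ± 0.11 (adjusted p = 1.02e-06). Here and below, slopes are means over 6 tumours, and the value after ± is the SE of limma, moderated across genes. Bhlhe41, a transcription factor of the circadian clock, had a slope of 2.94 ± 0.17, and Bace2, a protease that processes the pigment protein PMEL, 2.59 ± 0.17. Ptgds and Hpgds, both synthases of prostaglandin D, rose by 2.69 ± 0.09 and 2.51 ± 0.15. Car14 and Fam174b rose by 2.27 ± 0.12 and 2.24 ± 0.13. The largest decrease was that of Bgn, which encodes biglycan, with a slope of -2.04 ± 0.20 (adjusted p = 0.000306). Mgp had -1.97 ± 0.18, Ltbp1 -1.96 ± 0.12, Fn1, which encodes fibronectin, -1.86 ± 0.12, and Lamb1, a laminin chain, -1.81 ± 0.14. Cp, which encodes ceruloplasmin, had -1.80 ± 0.15, the water channel Aqp1 -1.72 ± 0.14, and the receptor tyrosine kinase Axl -1.64 ± 0.24 (adjusted p = 0.00214, from -2.83 to -0.92 over the tumours). These 16 genes were named among those with 1 sign in all 6 tumours, so their agreement in sign is set by the rule.

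By list, oxidative phosphorylation rose and mesenchymal and neural crest-like genes fell as the melanocytic score rose. Of 29 measured oxidative phosphorylation genes, 23 rose and 0 fell, and 6 did not pass (27 rose when adjusted over the list alone; camera adjusted p = 6.8e-14, adjusted p = 0.386 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, had a slope of 1.96 ± 0.12 and Idh3a, of the citric acid cycle, 0.89 ± 0.15. Of 19 hypoxia and glycolysis genes, 10 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.000241, 0.903 without the covariate of detected genes, adjusted p = 0.48 with an estimated correlation), with Pdk1 at 0.91 ± 0.14 and Hk2, a hexokinase, at 0.84 ± 0.11. Of 12 mesenchymal genes, 8 fell and 0 rose (10 fell adjusted over the list alone; camera adjusted p = 3.37e-06, adjusted p = 0.386 with an estimated correlation), among them Tnc, which encodes tenascin C, at -1.41 ± 0.14. Of 8 neural crest-like genes, 4 fell and 0 rose, the same 4 and 0 adjusted over the list alone (camera adjusted p = 0.0133, adjusted p = 0.386 with an estimated correlation), with the transcription factor Tfap2b at -1.63 ± 0.14 and Nes at -0.98 ± 0.13.

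Along the melanocytic score camera also called the MHC class I, type I interferon, immediate early, S phase and G2/M lists as lower, with few members of each past the test. Of 16 MHC class I genes, 5 fell and 0 rose (7 fell adjusted over the list alone; camera adjusted p = 2e-04, adjusted p = 0.48 with an estimated correlation), with the immunoproteasome genes Psmb8 at -1.20 ± 0.23 and Psmb9 at -1.09 ± 0.23 and the peptide transporter Tap1 at -0.82 ± 0.23. Of 8 type I interferon-stimulated genes 1 fell, Bst2 at -0.47 ± 0.12, and 0 rose (3 fell adjusted over the list alone; camera adjusted p = 0.00927, 0.079 without tumour 122, adjusted p = 0.497 with an estimated correlation). Of 19 immediate early genes, 6 fell and 0 rose (9 fell adjusted over the list alone; camera adjusted p = 5.2e-05, 0.0587 without cluster 6, adjusted p = 0.48 with an estimated correlation), led by Nr4a1 at -1.52 ± 0.09 and Klf4 at -0.96 ± 0.11. Of 33 S phase genes, 5 fell and 0 rose (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000192, adjusted p = 0.48 with an estimated correlation), such as Mcm4 at -0.46 ± 0.11. Of 36 G2/M genes, 2 rose, Psrc1 and Gas2l3 at 0.87 ± 0.11 and 0.74 ± 0.10, and 1 fell, Anln at -0.63 ± 0.15 (2 and 1 adjusted over the list alone; the list as a whole was lower, camera adjusted p = 0.00167, adjusted p = 0.574 with an estimated correlation). Without the covariate of detected genes, the S phase and G2/M lists turned to higher and did not pass (camera adjusted p = 0.0741 and 0.125). The edgeR test called 20 oxidative phosphorylation, 7 mesenchymal, 6 neural crest-like and 12 immediate early genes, but 2 MHC class I genes, 1 hypoxia gene, and 0 of the type I interferon, S phase and G2/M lists, where 0, 7 and 0 had an unadjusted p under 0.05.

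The other 6 lists did not pass camera along the melanocytic score, though single members did. In the list of HGF, MET and MAPK output, 3 of 16 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.373). Met, the receptor of hepatocyte growth factor, rose by 2.05 ± 0.24 (adjusted p = 0.000748), and Spry1, a feedback inhibitor of receptor tyrosine kinases, had a slope of -1.27 ± 0.18. In the list of immune-inhibitory genes 2 of 11 rose and 1 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.812). Cd274, which encodes PD-L1, rose by 1.07 ± 0.14 and Lgals3, a galectin, by 1.35 ± 0.33, although the slope of Lgals3 was -0.83 in the lowest tumour. Cd274 is also in the interferon-gamma list, in which it was the 1 gene of 7 that rose, and Irf1, at -0.57 ± 0.15, the 1 that fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.33). Among melanoma suppressors and oncogenes 2 of 17 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.986), with Cdk6, a kinase of the G1 phase, at -1.48 ± 0.16. Among p53 targets 3 of 16 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.408), with the cell cycle inhibitor Cdkn1a at -0.95 ± 0.15. Among unfolded protein and integrated stress response genes 2 of 16 rose and 2 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.138), with Ddit3 at 0.77 ± 0.17.

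In total 1509 of 10744 genes passed along the melanocytic score by limma, 871 up and 638 down, 1332 of them with 1 sign in all 6 tumours. Cells of cluster 6 have few melanocytic transcripts, and without them 910 genes passed. Cluster 2, found in all 6 tumours, was low too. Outside tumour 122 its mean log2(CPM + 1) was 1.78 over the melanocytic list, against 5.99 in melanoma-like cells. For oxidative phosphorylation it was 5.77 against 7.71, and for neural crest-like genes 3.61 against 1.59. Slopes and list calls can therefore follow this contrast of clusters. List tests among melanoma-like cells alone are not reported here. Among melanoma-like cells of 6 tumours 130 genes passed, with 13 such cells in tumour 122, and 1344 passed among those of the other 5 tumours, 678 of them shared with the 1509. An edgeR test of summed counts of cells above and below the median score called 564, and 5432 were called when the number of detected genes was not a covariate. Leaving out tumour 103, 109, 115 or 117 gave 912, 970, 915 and 970 genes.

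**Figure D3:**
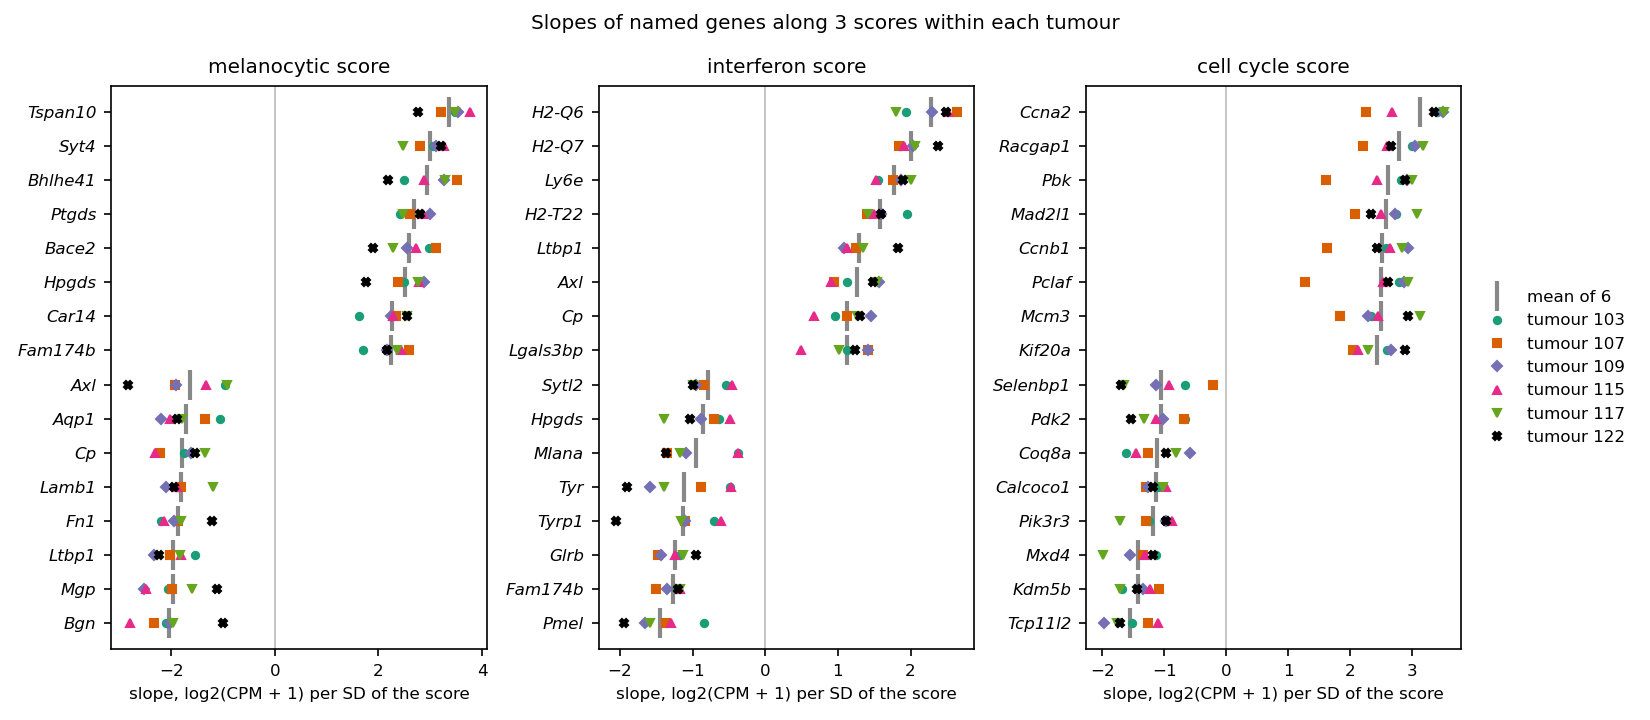
Slopes of the named genes (horizontal axis, log2(CPM + 1) per SD of the score) along the melanocytic, interferon and cell cycle scores, with 1 symbol per tumour and a grey bar at the mean of 6. The genes shown were chosen among those with 1 sign in all 6 tumours, so their lying on 1 side of 0 is set by the rule. Slopes of Tspan10 along the melanocytic score range from 2.77 to 3.76.

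The second comparison asked which genes follow interferon response and antigen presentation. The interferon score was the mean of 23 measured genes of MHC class I presentation and interferon-gamma response, such as B2m and Tap1. Of the genes outside the score, further MHC class I genes rose along it, H2-Q6 by 2.28 ± 0.13 (limma with Benjamini-Hochberg adjustment, adjusted p = 5.17e-05), H2-Q7 by 2.01 ± 0.10 and H2-T22 by 1.58 ± 0.10. These 3 have near-identical copies, so reads may have been split between them, and their values are uncertain. The score itself holds H2-K1, H2-D1, H2-Q4 and H2-T23. Reads shared with these could raise the 3 slopes, which was not tested. Ly6e, an interferon-induced membrane protein, rose by 1.77 ± 0.09. Ltbp1, Axl and Cp, named above as lower along the melanocytic score, rose here by 1.29 ± 0.12, 1.26 ± 0.13 (adjusted p = 0.00216) and 1.13 ± 0.12. Lgals3bp rose by 1.12 ± 0.12. Pigment genes fell, with Pmel at -1.45 ± 0.12 (adjusted p = 0.000613), Tyrp1 at -1.13 ± 0.16, Tyr at -1.12 ± 0.19 and Mlana at -0.95 ± 0.16. Fam174b at -1.27 ± 0.10, the glycine receptor gene Glrb at -1.24 ± 0.10, Hpgds at -0.85 ± 0.13 and Sytl2 at -0.79 ± 0.12 also fell. Pmel shares exons with Cdk2 and Dgka on the opposite strand, so part of its counts cannot be assigned to 1 strand.

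Along the interferon score the type I interferon, mesenchymal and immediate early lists rose and the melanocytic list fell. Of 8 type I interferon-stimulated genes, 3 rose and 0 fell (7 rose adjusted over the list alone; camera adjusted p = 5.65e-07, adjusted p = 0.386 with an estimated correlation), with Bst2, which tethers virions at the cell surface, at 1.09 ± 0.10 and Xaf1 at 0.75 ± 0.13. Of 12 mesenchymal genes, 2 rose and 0 fell (4 rose adjusted over the list alone; camera adjusted p = 2.01e-06, 0.0741 without the covariate of detected genes, adjusted p = 0.405 with an estimated correlation), Axl and Fn1, the latter by 0.67 ± 0.11. Of 19 immediate early genes, 2 rose and 0 fell (13 rose adjusted over the list alone; camera adjusted p = 4.03e-07, adjusted p = 0.441 with an estimated correlation), among them Fos by 1.10 ± 0.19. This list marks stress of dissociation as well as signalling. Of 16 melanocytic genes, 4 fell and 0 rose (10 fell adjusted over the list alone; camera adjusted p = 0.000192, adjusted p = 0.48 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 0 passed by limma over all genes and 0 by edgeR, with 10 and 8 at an unadjusted p under 0.05, and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000143, down; adjusted p = 0.405 with an estimated correlation). Of 33 S phase genes 0 passed by limma, over all genes or adjusted over the list alone, and 0 by edgeR, with 2 and 2 at an unadjusted p under 0.05 and a median slope of -0.07 (camera adjusted p = 0.0244, down; adjusted p = 0.678 with an estimated correlation). The call of the S phase list was lost without tumour 115, 117 or 122 (camera adjusted p = 0.0738, 0.584 and 0.193) and without cluster 6 (0.0504), and its direction turned to higher without the covariate of detected genes (0.521). In the type I interferon, mesenchymal, immediate early and melanocytic lists edgeR also called 0 genes. There 2, 2, 2 and 1 had an unadjusted p under 0.05 in edgeR.

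The other 8 lists did not pass camera along the interferon score, with adjusted p from 0.0815 for oxidative phosphorylation to 0.812 for the unfolded protein and integrated stress response. Without tumour 122 oxidative phosphorylation passed as lower and the neural crest-like list as higher (camera adjusted p = 0.0462 and 0.0492), the latter also without cluster 6 (0.0104), but without the covariate of detected genes oxidative phosphorylation passed as higher (0.000251). The G2/M list passed as lower without tumour 103 or 115 (0.00342 and 0.0159). In the neural crest-like, G2/M phase, oxidative phosphorylation, unfolded protein and p53 target lists 0 genes passed by limma over all genes tested, with 4 of 8, 3 of 36, 5 of 29, 6 of 16 and 3 of 16 at an unadjusted p under 0.05, and 0 by edgeR. Adjusted over the list alone, 2 rose and 3 fell in the unfolded protein list and 0 passed in the other 4. In the immune-inhibitory list 1 of 10 rose, Tgfb2 by 0.51 ± 0.10, and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.176). Myc, at -0.37 ± 0.07, was the 1 gene that fell in the list of HGF, MET and MAPK output (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.461). It was also the 1 that fell among melanoma suppressors and oncogenes, where Cdk6 was the 1 that rose, by 0.81 ± 0.13 (1 and 1 adjusted over the list alone; camera adjusted p = 0.721).

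In total 95 of 10737 genes passed along the interferon score by limma, 71 up and 24 down, each with the same sign in all 6 tumours, and 1555 had an unadjusted p under 0.05. This count is less firm than the others: 3 of 20 random lists of like expression called as many genes or more, and the edgeR test of cells above and below the median score called 0, with 718 at an unadjusted p under 0.05. Leaving out tumour 103, 107, 109, 115 or 117 gave 37, 42, 36, 37 and 32 genes, and a correlation of ranks called 433, of which 47.8% rose against 74.7% of the 95. Among melanoma-like cells 8 genes passed, 3 up and 5 down, and 1.4e2 (rounded) among those outside tumour 122. Cluster 6 had a mean log2(CPM + 1) of 6.47 over MHC class I genes, against 4.48 in melanoma-like cells. For mesenchymal genes it was 4.26 against 1.90, and for melanocytic genes 1.12 against 5.99. Slopes and list calls can therefore follow contrasts of clusters here too, most of all in tumour 122, which holds most of cluster 6.

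**Figure D4:**
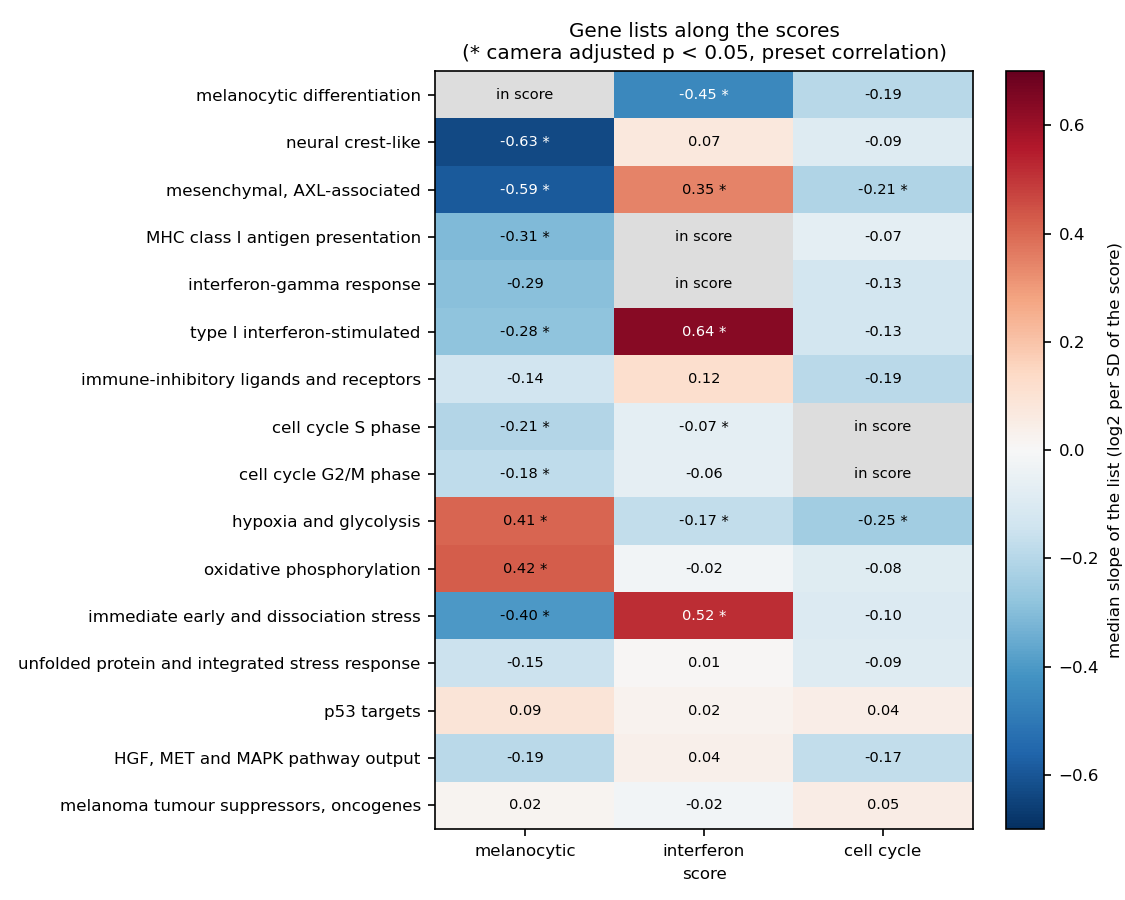
Median slope of each fixed list (colour and number, log2 units per SD) along the 3 scores, with a star where camera with a preset correlation gave an adjusted p under 0.05. Oxidative phosphorylation and hypoxia genes are positive along the melanocytic score at 0.42 and 0.41, and type I interferon genes reach 0.64 along the interferon score.

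The third comparison asked which genes follow the cell cycle, scored over 69 measured genes of the S and G2/M phases. Of the genes outside the scored lists Ccna2, which encodes cyclin A, rose most, by 3.12 ± 0.17 (limma with Benjamini-Hochberg adjustment, adjusted p = 7.62e-06). The cytokinesis gene Racgap1 rose by 2.78 ± 0.15, the mitotic kinase Pbk by 2.61 ± 0.17, the spindle checkpoint gene Mad2l1 by 2.57 ± 0.14, Ccnb1, which encodes cyclin B, by 2.51 ± 0.16, Pclaf by 2.50 ± 0.20, the replicative helicase gene Mcm3 by 2.49 ± 0.17 and the kinesin Kif20a by 2.43 ± 0.12. Tcp11l2 fell most, with a slope of -1.56 ± 0.12 (adjusted p = 4.54e-05). Mxd4, an antagonist of MYC, had -1.42 ± 0.12 and Kdm5b, a histone demethylase, -1.42 ± 0.10. Further decreases were in Pik3r3, a regulatory subunit of PI3 kinase, at -1.18 ± 0.12, Calcoco1 at -1.14 ± 0.07, Coq8a, which acts in coenzyme Q synthesis, at -1.12 ± 0.14, Pdk2, a pyruvate dehydrogenase kinase, at -1.06 ± 0.14, and Selenbp1 at -1.05 ± 0.18. Pik3r3 shares exons with a predicted gene on the same strand and was near 0, at 0.01 (adjusted p = 0.983), in the edgeR test.

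Along the cell cycle score 8 of 19 hypoxia genes fell and 0 rose, while edgeR called 3 (13 fell adjusted over the list alone; camera adjusted p = 2.81e-05, adjusted p = 0.386 with an estimated correlation), with Ndrg1 at -0.87 ± 0.13, Bnip3, a mitophagy receptor, at -0.74 ± 0.14 and Ankrd37 at -0.48 ± 0.14. Of 12 mesenchymal genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.0279, 0.0965 without tumour 122 and 0.544 without cluster 6, adjusted p = 0.48 with an estimated correlation), among them Thbs1, which encodes thrombospondin, at -0.61 ± 0.12. The other 12 lists did not pass camera, with adjusted p from 0.055 for the melanocytic list to 0.807 for p53 targets. The melanocytic list passed as lower without tumour 109 or 122 (camera adjusted p = 0.00848 and 0.00707) and without cluster 6 (8.25e-05). Oxidative phosphorylation did so without tumour 107 or 109 (0.0082 and 0.0264) or cluster 6 (0.00501), but passed as higher without the covariate of detected genes (1.31e-05). The immediate early list passed as lower without tumour 107, 115 or 117 (0.0361, 0.0394 and 0.039), and this list and the neural crest-like list did so without that covariate (0.000251 and 0.00036). Among them, 2 of 16 melanocytic genes fell, Cited1 at -0.54 ± 0.12 and Trpm1 at -0.56 ± 0.16 (4 adjusted over the list alone), and 1 of 16 MHC class I genes, H2-T23 at -0.86 ± 0.12 (1 adjusted over the list alone). Of 11 immune-inhibitory genes, 2 fell, Cd47, the signal against phagocytosis, at -0.54 ± 0.09 and Lgals3 at -0.61 ± 0.13 (2 adjusted over the list alone). Of 19 immediate early genes 3 fell, such as Dusp1 at -0.69 ± 0.14 and Junb at -0.63 ± 0.11 (6 adjusted over the list alone). In the unfolded protein and integrated stress list 1 of 16 rose, Psat1, of serine synthesis, by 1.03 ± 0.19, and 4 fell, such as Xbp1 at -0.81 ± 0.11 (3 and 6 adjusted over the list alone). In the list of HGF, MET and MAPK output 1 of 16 rose, Etv4, a transcription factor downstream of MAPK signalling, by 0.60 ± 0.12, and 3 fell, such as Met at -0.50 ± 0.08 (2 and 7 adjusted over the list alone). Of 16 p53 targets 3 fell, such as Sesn1 at -0.58 ± 0.14 (4 adjusted over the list alone). Of 29 oxidative phosphorylation genes 1 fell, Ndufs3 at -0.35 ± 0.08 (0 adjusted over the list alone, 7 at an unadjusted p under 0.05, 9 called by edgeR), and of 8 type I interferon-stimulated genes 1 rose, Ifit2 by 0.56 ± 0.16 (1 adjusted over the list alone). Among 17 melanoma suppressors and oncogenes Hras rose by 0.40 ± 0.12 and Map2k1 fell, at -0.43 ± 0.09 (0 and 1 adjusted over the list alone). In the neural crest-like and interferon-gamma lists 0 genes passed by limma over all genes or adjusted over the list alone, with 3 of 8 and 0 of 7 at an unadjusted p under 0.05, while edgeR called 2 and 1 (camera adjusted p = 0.681 and 0.332).

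In total 1611 of 10691 genes passed along the cell cycle score, 866 up and 745 down, 1386 of them with 1 sign in all 6 tumours. The count was 913 without cluster 6, 553 among melanoma-like cells of 6 tumours and 1480 among those of the 5 tumours other than tumour 122, 1141 of them shared with the 1611. It was 800 in the edgeR test and 5595 when the number of detected genes was not a covariate. Leaving out tumour 103, 109, 115 or 117 gave 1017, 1058, 1025 and 1001 genes. Over the 3 scores camera called 17 of 43 pairs of list and score, 5 up and 12 down; 0 held with an estimated correlation, where 5 had an unadjusted p under 0.05, and 6 held with fry. In 8 pairs, of which camera called 0, the median, the mean and the direction of the test differed in sign.

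The genes with the largest slopes lie on several chromosomes of the GRCm38 assembly. Tspan10 (ENSMUSG00000039691.10) lies on chromosome 11 from 120442644 to 120446950, Syt4 (ENSMUSG00000024261.6) on chromosome 18 from 31437808 to 31447406, Bgn (ENSMUSG00000031375.17) on chromosome X from 73483602 to 73495933 and Ltbp1 (ENSMUSG00000001870.16) on chromosome 17 from 75005568 to 75392512. Axl (ENSMUSG00000002602.16) lies on chromosome 7 from 25757273 to 25788705, Pmel (ENSMUSG00000025359.10) on chromosome 10 from 128704195 to 128720238, Met (ENSMUSG00000009376.15) on chromosome 6 from 17463800 to 17573980 and Ccna2 (ENSMUSG00000027715.9) on chromosome 3 from 36564865 to 36572150. H2-Q6 and H2-Q7 are neighbours on chromosome 17, from 35424850 to 35430055 and from 35439155 to 35443773. All these are protein-coding genes, and the values are sums over their annotated transcripts. Exons of Syt4, Bhlhe41, Car14, Fam174b, Fn1, Cp, H2-T22, Ccna2, Kif20a, Mxd4 and Coq8a overlap a gene on the opposite strand. So do exons of several list members, such as Psmb9 and Tap1, which overlap each other. The library method does not keep the strand, so the part of their counts in the overlap is uncertain.

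Between tumours, tumour 122 stood apart in 6 of the 16 lists. Its melanocytic list had a mean log2(CPM + 1) of 5.91, against 7.99 to 8.23 in the other 5 tumours, with 18 of 20 genes lowest there, such as Cited1 at 22.8 CPM against 327 to 462. Type I interferon-stimulated genes averaged 6.50 against 2.65 to 3.45, with 20 of 20 genes highest in tumour 122. Ifi44 was at 113.4 CPM there and at most at 0.84 elsewhere. The difference to the median of the other 5 was -2.17 for the melanocytic and 3.38 for the type I interferon list. It was 1.55 for the mesenchymal list, with 19 of 23 genes highest, such as Axl at 416 CPM against 25.2 to 104.7. Some fibroblast markers moved with it: in cluster 6 Col3a1 was detected in 100% of cells, Pdgfra in 59.1% and Dcn in 48.5%, against 28.8% for Col1a1 and 9.1% for Col1a2. Cluster 6 met 4 of the 12 fibroblast markers, too few for that name. The difference was 1.23 for MHC class I presentation, with 15 of 16 highest, such as Psmb8 at 400.1 CPM against 38.6 to 81.8. The interferon-gamma list is not 1 of the 6, although its difference was 1.17. Its level was 4.42 in tumour 122 and 3.96 in tumour 109, whose plates reached 4.19. Of its genes 14 of 25 were highest in tumour 122, such as Cxcl10, a chemokine that attracts T cells, at 374 CPM against 4.42 to 31.9. Hypoxia and glycolysis genes were lower, with a difference of -1.42 and 18 of 21 lowest, such as Ero1l at 81.7 CPM against 468 to 783, and so were oxidative phosphorylation genes, with -0.59 and 28 of 29 lowest, such as Ppargc1a at 38.3 CPM against 165.9 to 210.5. The differences of the other 9 lists lay between -0.62 for the unfolded protein response and 0.79 for immediate early genes, with 0.62 for neural crest-like, 0.45 for S phase, 0.21 for G2/M, 0.18 for immune-inhibitory, -0.09 for p53 target, -0.02 for HGF, MET and MAPK and 0.05 for suppressor and oncogene lists.

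Without the cells of cluster 6, tumour 122 kept 26 tumour cells, 13 of them in cluster 2 and 6 in cluster 4. Cell cycle genes such as Ccna2 led cluster 4. Cluster 2 of the other tumours had a melanocytic mean log2(CPM + 1) of 1.78, against 5.99 in melanoma-like cells. The differences without cluster 6 thus rest on few cells and can follow their mix of clusters. Of the 16 differences, 7 were then smaller in size and 9 larger. The difference of tumour 122 was then -0.68 for the melanocytic list, 0.94 for type I interferon, 0.25 for mesenchymal, 0.14 for MHC class I, 0.34 for interferon-gamma, -0.10 for immune-inhibitory and -0.17 for oxidative phosphorylation genes. The hypoxia difference of -1.57 was not smaller, and that of immediate early genes changed sign to -2.19, as did the immune-inhibitory one. Those of the S phase and G2/M lists were larger, at 1.20 and 0.92, as were those of the neural crest-like list at 0.73, the unfolded protein list at -0.69, p53 targets at -0.28, HGF, MET and MAPK output at -0.42 and suppressors and oncogenes at -0.13, the last with a change of sign. Within tumour 122 itself, cluster 6 cells had a mean log2(CPM + 1) of 3.97 over the type I interferon list, against 1.12 in the 6 cluster 6 cells of other tumours. Cells of cluster 2 had 2.49 in tumour 122 and 1.14 elsewhere, while melanoma-like cells differed by 0.06.

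**Figure D5:**
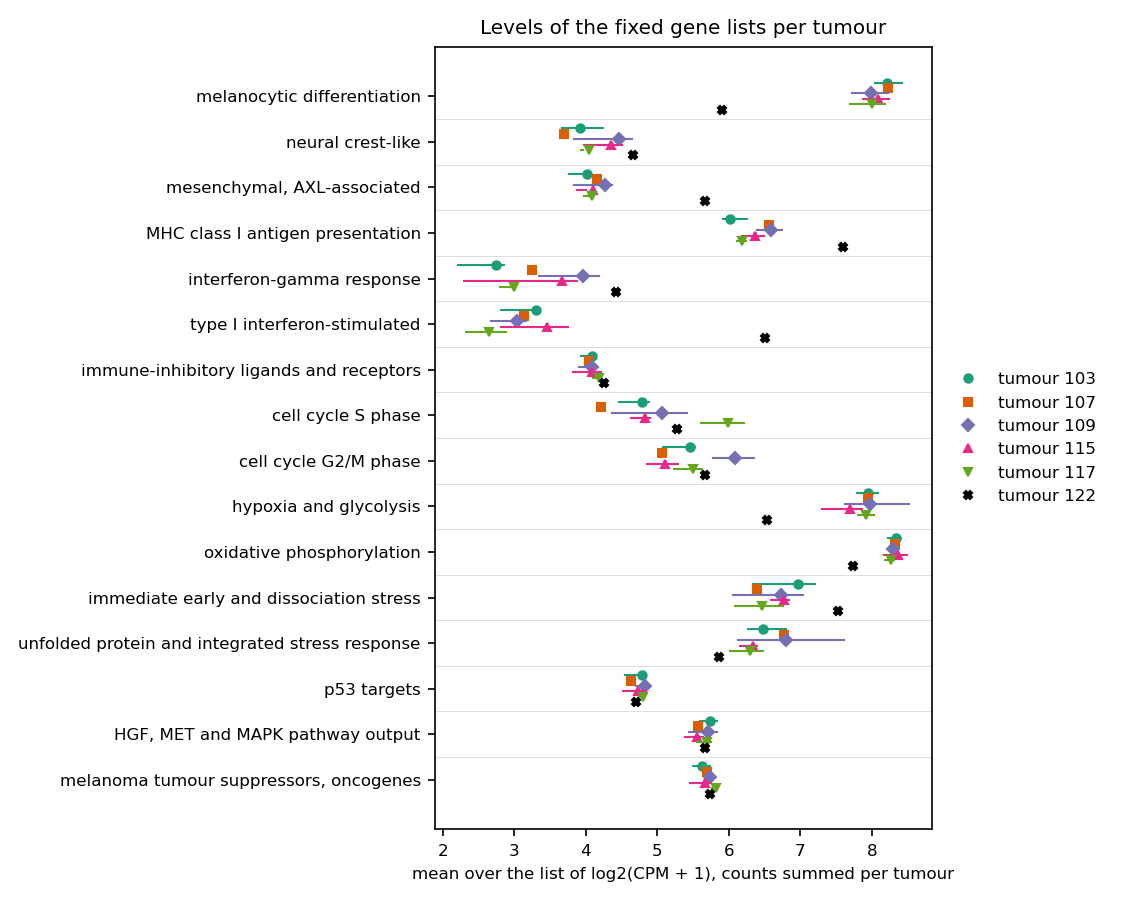
Mean log2(CPM + 1) of each fixed list (horizontal axis) in the summed tumour cells of each tumour, with lines over the range of plates where a tumour has several. Tumour 122 lies apart in type I interferon genes, at 6.50 against at most 3.45, and in melanocytic genes, at 5.91 against at least 7.99.

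Single genes set the tumours apart as well. In tumour 122 the largest excesses were of Crabp1, a retinoic acid-binding protein, at 1428 CPM against 0 to 13.6 elsewhere, of the Wnt ligand gene Wnt10a at 608 CPM against 0 to 27.6, and of Ccn5 at 372 CPM against 0 to 1.07. These are also leading genes of cluster 6, so that they and its share are 1 observation. Fgl2 at 5.56 CPM against 178.1 to 477 and the glycolytic aldolase gene Aldoc at 5.95 against 233.7 to 318 were lower there. Met was at 134.4 CPM in tumour 122 and between 491 and 622 in the others, and Hgf between 1.05 and 2.88 in all 6. In tumour 117 the S phase list was highest, at 5.99 against 4.21 in tumour 107. Ccne2, Rrm2 and Dtl exceeded the median of the other tumours by 2.21, 2.05 and 1.96 on the log2 scale, and Tcim and Usf3 lay at -2.17 and -1.52. In tumour 107 Pola1 and Ndc1 were lower, at -2.81 and -2.56. Thbs2, Bgn and Fgfr1 were higher there by 2.23, 2.16 and 2.09, but at -0.43, -0.57 and -1.63 without its 2 cells of cluster 6. In tumour 103 the heat shock gene Hspa1a was higher by 1.55, Enpp2 by 1.14 and Pygl by 1.11, and Apod and Thbs2 lay at -1.68 and -1.44. In tumour 109 Apod was higher by 1.82, Aasdh by 1.36 and Rarb by 1.24, and Eml1 and Hivep1 lay at -1.56 and -1.49, Hivep1 with the opposite sign, 0.69, in deposited TPM. In tumour 115 Gpr37l1 was higher by 1.48 and Pygl by 1.41, and Top2a and Gtpbp2 lay at -1.41 and -1.27. In deposited TPM the ratios of Hspa1a and Pygl in tumour 103 were 0.70 and 0.10, that of Pygl in tumour 115 was 0.49, and those of Ccne2, Rrm2 and Dtl in tumour 117 were 1.02, 1.13 and 1.17. Of 30 such ratios, 22 moved over 1.5-fold in deposited TPM and 26 as means over cells, so their sizes are uncertain. Each tumour comes from 1 mouse, so none of these differences has a replicate. Hspa1a has a near-identical copy, Hspa1b, and its value is uncertain.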

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

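Of the tests below, those on host cells, on random gene lists and on choices of sign were chosen after the result was seen; those on plate, depth, missed detection and X-linked copies were written down before. In 15 of 72 groups of 6 tumours the highest or lowest tumour lay apart. There its gap to its neighbour, as a share of the whole range, was above the 95% critical value of Dixon's test. Chance gives about 1 in 20 among independent groups, which these are not, so the 15 cannot be set against it. In 10 of the groups outside the slopes, which share 1 plate and in part the same cluster 6 cells, tumour 122 was the tumour apart. Its gap as a share of the range was 0.897 for the melanocytic list (low), 0.842 for the mesenchymal list (high), 0.639 for MHC class I presentation (high), 0.792 for type I interferon genes (high), 0.807 for hypoxia and glycolysis (low), 0.855 for oxidative phosphorylation (low), 0.718 for the share of wells kept (high), 0.915 for the melanoma-like share (low), 0.955 for the share of cluster 6 (high) and 0.846 for Met (low).

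For tumour 122 and its cluster 6, host fibroblasts are argued against by Xist, detected in 3.0% of cluster 6, and Y-linked genes, in 1.5%. Xist was detected in 87.9% of fibroblast- and pericyte-like cells. Only 3 of those came from tumour 122, 1 with Xist (33.3%, interval 0.8% to 90.6%) and 0 with a Y-linked gene. How well these genes mark host cells of that tumour is therefore uncertain, which limits the argument. Col3a1, Pdgfra and Dcn were detected in 100%, 59.1% and 48.5% of cluster 6, but Col1a2 averaged 2.52 CPM there against 14454 in the fibroblast-like cluster, and Col1a1 208.7 against 17695. Of 140 cells of other tumours below the median depth of tumour 122, 0 fell into cluster 6, which allows up to 2.6%. Low depth alone thus did not place these cells in it. As 60 of the 66 cells of cluster 6 came from tumour 122, a low share was largely set in advance. Whether depth adds to the difference of tumour 122 therefore cannot be decided from this. A difference of the whole plate cannot be told apart from the tumour, which has 1 plate: over 696 genes that differed at least 4-fold, cluster 2 cells of tumour 122 kept a median of 31.9% of the difference (quartiles 7.0% and 60.5%) and melanoma-like cells 10.7% (quartiles -5.1% and 36.8%), with 13 cells of tumour 122 in each, though clusters were formed on expression, so that these are the cells most like those of other tumours. That a different cell state or the treatment of this mouse may be the source was not tested, since the labels do not give its treatment.

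The counts of genes along the scores were set against random lists and choices of sign. Along the melanocytic score 0 of 20 random lists of like expression called as many as 1509 genes (highest 724), and along the cell cycle score 0 of 20 called as many as 1611 (highest 33), so these counts lie beyond those of the lists drawn. The draws were matched on mean expression, not on how far their genes vary together. They therefore do not show that the counts are particular to these scores. Along the interferon score 3 of 20 called at least 95 (highest 306), so that its count may say no more than that of an arbitrary list. The fixed lists were not tested along the random scores, so this limit may also hold for the list calls. Turning the signs of the slopes of whole tumours gives 32 choices, and 1 of 32, the real one, gave as many genes for each score, with 99, 4 and 0 as the highest of the others. The same held for 30 of the 30 random lists, of 60, that called any gene, so that the choices of sign say nothing about a score.

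In 5 of 48 named slopes 1 tumour lay apart. The gap as a share of the range was 0.67 for Car14 along the melanocytic score, lowest in tumour 103, and 0.689 for Lamb1, highest in tumour 117. It was 0.636 for H2-T22, highest in tumour 103, and 0.649 for Ltbp1, highest in tumour 122, along the interferon score, and 0.754 for Pclaf along the cell cycle score, lowest in tumour 107. The deposited list of expressed variants, which no comparison used, holds 1969253 calls.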

How the results depend on the processing

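Settings named as without cluster 6, without cluster 9 and without tumour 122, for levels or for melanoma-like cells, were chosen after seeing the data. For 48 named genes, 993 of 1068 values under other settings kept direction and call, 74 lost the call and 1 changed sign, Pik3r3 along the cell cycle score in edgeR at 0.01265 (adjusted p = 0.983; from edgeR, not the slopes); the cause was not tested. Of those that lost it, 26 were in edgeR and 17 among melanoma-like cells, where tumour 122 has 13. The melanocytic, interferon and cell cycle counts of 1509, 95 and 1611 moved over 1.5 times as follows. Without the covariate of detected genes they were 5432, 738 and 5595, mostly up (92.6%, 98.6% and 95.8%), with a median slope over genes of 0.22, 0.15 and 0.24. With edgeR they were 564, 0 (718 at an unadjusted p under 0.05) and 800, among melanoma-like cells 130, 8 and 553, but 1344, 1.4e2 and 1480 without tumour 122 and its 13 such cells. The first count was 857 with the 25% filter, 2267 with all kept cells and 910 without cluster 6, the last 913 without cluster 6. The interferon count was 433 by ranks, 49 with a pseudocount of 10, 1.6e2 and 38 with filters at 25% and 1%, which change the genes tested, 210 with all kept cells and 1.5e2 weighted by cells (values in powers of 10 are rounded). Leaving out 1 tumour gave 912 to 1817, 32 to 1.4e2 and 1001 to 1716, with fewer samples. The highest of these were rises, 1817 and 1.4e2 without tumour 122 and 1716 without tumour 107. The cause of these rises and of the other moves was not tested. Of the 1509, 95 and 1611 genes, 1480, 86 and 1492 were shared with scran scaling and 427, 0 and 398 with edgeR. Of 17 calls of lists, 0 held with an estimated correlation, 6 with fry and 17 to 19 calls were made without 1 tumour. These were not always the same lists: without tumour 122, 3 calls were lost (type I interferon along the melanocytic score, S phase along the interferon score, mesenchymal along the cell cycle score) and 3 gained (neural crest-like and oxidative phosphorylation along the interferon score, melanocytic along the cell cycle score). Without cluster 6, 3 were lost (immediate early along the melanocytic score and the same S phase and mesenchymal calls) and 3 gained (neural crest-like along the interferon score, melanocytic and oxidative phosphorylation along the cell cycle score). Without the covariate of detected genes, 5 were lost and 4 gained, and 5 of these turned direction, all from lower to higher, cause not tested. The lost calls were S phase (0.0741, turned), G2/M (0.125, turned) and hypoxia (0.903) along the melanocytic score and S phase (0.521, turned) and mesenchymal (0.0741) along the interferon score. The gained calls were oxidative phosphorylation along the interferon (0.000251, turned) and cell cycle scores (1.31e-05, turned), and neural crest-like (0.00036) and immediate early genes (0.000251) along the cell cycle score. The median range of list levels, 1.085 log2 units, was 0.393 without tumour 122, and the difference of immediate early genes in tumour 122 turned to -2.193 without cluster 6. In tumour 107, Thbs2, Bgn and Fgfr1 turned to -0.43, -0.57 and -1.63 without cluster 6, 2 cells of that tumour, and to -0.42, -0.52 and -1.15 as means over cells, which weigh these 2 cells less. Hivep1 in tumour 109 turned to 0.69 in TPM, cause not tested. Of 180 values of genes named between tumours, 41 moved beyond the spread of plates without a change of sign. Of the list differences of tumour 122 over all settings, 27 moved beyond that spread besides the reversal of immediate early genes, 4 of them with a change of sign: immune-inhibitory to -0.10 and suppressors and oncogenes to -0.13 without cluster 6, the latter to -0.09 with all kept cells, and G2/M to -0.19 as a mean over cells. The melanoma-like share of tumour 109 was 68.6% at the doubled resolution. At the halved resolution the pericyte- or smooth muscle-like class held 0 cells in all 6 tumours, and the fibroblast-like share was higher in each, such as 3.1% against 1.0% in tumour 103 and 3.4% against 1.1% in tumour 122. Alternatives for expressed mutations were not run, as calls could not be tied to cells. No paired analysis was possible by replicate number, because these numbers only name cells in accession order; the edgeR test pairs sums within a tumour. Depth per cell, lowest in tumour 122, limits the detection of low genes.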

Other observations

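The score of Y-linked genes, its list tests, random lists and left-out tumours were chosen after the data were seen; the tests on missed detection and X-linked copies were written down before. Along a score of Ddx3y, Eif2s3y, Uty and Kdm5d, over the 5 tumours other than tumour 122, 431 of 11200 genes passed (limma with Benjamini-Hochberg adjustment), 56.1% of them up. Of 20 random lists of 4 genes of like expression, 0 called as many (highest 28). These lists were not matched on how far their genes vary together. The comparison therefore does not show that the count is particular to Y-linked genes. Without tumour 103, 107, 109, 115 or 117 the count was 1.6e2, 372, 1.4e2, 1.5e2 and 1.1e2 (values in powers of 10 are rounded), and it was 453 without the covariate of detected genes. The edgeR test was not run for this score. A Y-linked gene was detected in 90.3% of cells of clusters 7 and 8 and in 9.0% of the other tumour cells. Leading genes that define these clusters include Slc16a3, Cd74 and H2-Aa in cluster 7 and Cdc20 and Ccna2 in cluster 8. The slopes and list calls that follow can therefore restate this contrast of clusters, which was not tested. Genes of antigen presentation rose, with H2-Q6 at 1.78, the peptide transporter Tap1 at 1.51 and the immunoproteasome genes Psmb8 and Psmb9 at 1.41 and 1.39 log2 units per SD, together with Ly6e at 1.67, the lactate transporter Slc16a3 at 1.44 and Fos at 1.41. Pigment genes fell, with Pmel at -1.59, Tyrp1 at -1.38, Mlana at -1.03 and Tyr at -1.02, as did Glrb at -1.63 and Spp1 at -1.03. By list, 11 of 16 MHC class I genes rose (camera adjusted p = 1.12e-11, adjusted p = 0.113 with an estimated correlation), 11 of 18 melanocytic genes fell (camera adjusted p = 5.79e-06, adjusted p = 0.113 with an estimated correlation) and 10 of 19 immediate early genes rose and 1 fell (camera adjusted p = 4.66e-08, adjusted p = 0.317 with an estimated correlation). Camera also called oxidative phosphorylation as lower (adjusted p = 4.66e-08, adjusted p = 0.122 with an estimated correlation) and the G2/M list as higher (adjusted p = 0.000159, adjusted p = 0.454 with an estimated correlation), each with 0 members past limma's test and 11 at an unadjusted p under 0.05. Of the other called lists, 4 of 20 hypoxia, 2 of 12 mesenchymal, 3 of 7 interferon-gamma and 1 of 8 type I interferon genes rose (camera adjusted p = 0.00083, 0.00258, 0.00594 and 0.044, and adjusted p = 0.454, 0.248, 0.248 and 0.454 with an estimated correlation). H2-Q6 has near-identical copies and its value is uncertain.

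A hypothesis is that clusters 7 and 8, present in 5 of the tumours, may belong to a subpopulation of tumour cells that transcribes Y-linked genes while most other tumour cells do not; 27.9% of cluster 2 detected such a gene too, so that the clusters do not bound it. Missed detection is argued against: outside clusters 7 and 8, genes matched to the level of each Y-linked gene in those clusters were detected in 59.9, 50.7, 43 and 27.3 percentage points more cells than Ddx3y, Eif2s3y, Uty and Kdm5d. Reads of the X-linked copies are argued against for the 4 genes as a set, since the mean difference of these copies was 8.3% of that of the Y-linked genes. This mean is over both signs. On the log2 scale Ddx3x was higher in clusters 7 and 8 by 0.80, against 3.66 for Ddx3y. Eif2s3x was higher by 0.12 against 3.35 for Eif2s3y and Kdm5c by 0.24 against 1.41 for Kdm5d, while Kdm6a lay at -0.26 against 2.45 for Uty. A Y-linked gene was detected in 3.0% of fibroblast- and pericyte-like cells. What sets these cells apart was not tested, nor was treatment.

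Over the whole series the list of expressed variants holds 1816265 distinct variants, of which 1710189 (94.2%) were listed once and 72 at least 50 times. Of the calls, 58.03% were nonsynonymous, 26.9% synonymous and 3.13% gains of a stop codon. C-to-T changes made up 49.3% of single-base variants listed once, 67.2% of those listed 2 to 9 times, 53.1% of those listed 10 to 49 times and 46.2% of those listed at least 50 times. These groups hold 1523916, 89263, 407 and 39 single-base variants, so the last 2 shares rest on few. Frameshift variants made up 10.2% of variants listed once, 14.2% of those listed 2 to 9 times, 52.6% of those listed 10 to 49 times and 43.1% of those listed at least 50 times. For these the last 2 groups hold 926 and 72 variants.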
